A study of Homo sapiens with 5 samples.

How the data were processed

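Total RNA of a single pool of human vastus lateralis biopsies, named in the labels as insulin sensitive pool 4, was measured on 5 Affymetrix array designs, 1 array each. The deposited tables hold 1 intensity per probe set, in whole numbers on a linear scale with many values below 0. The scanner settings, the summary method and any scaling are not given in the sources used here, and no detection calls were used. From the values, the arrays had not been brought to a common scale. The 5 arrays formed the single group of the study and were treated as technical measurements of 1 sample. The number of arrays limits the precision, and no test between conditions was possible. All sample columns were used.

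Genes were named through the platform annotation supplied for each design, with symbols updated through the Entrez ID against a RefSeq gene table for the assembly GRCh38.p14, which was used for names only. No genome build is given in the sources used here, and no coordinates are printed. Of 42553 probe sets besides controls, 29711 named a single gene, 857 named several genes and 11985 named none in the annotation used. The Entrez ID was found in the gene table for 29636 of the 29711, and the annotation's own symbol was kept for the others. Probe sets with several genes or none were ranked with their array and were not named. Y-linked and X-inactivation genes were left out of the genes named.

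The percentile of each probe set was its rank among all non-control probe sets of its own array, so that no scaling between arrays was needed. The noise floor of an array was the size of its 1st percentile, mirrored above 0, and was 735 on subA, 203 on subB, 281.3 on subC, 381.3 on subD and 631.2 on HuFL. By construction, 1% of the values of an array lay below 0 by more than its floor, so a signal just above the floor can still be noise. Exact values of 0 on HuFL included genes that every cell uses, and were reported only as listed at 0.

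The 25 gene lists (12 of pathways and 13 of cell types, 515 genes in all, no gene in over 1 list) were fixed before the data were examined, as were the rule for naming genes and the first set of alternatives. Of the 515 genes, 67 were matched to no single-gene probe set, 20 of them because they were named only in probe sets of several genes. In addition, 1 gene was found under an updated symbol. NDUFA4 was among the unmatched genes, because its probe sets carried the newer symbol COXFA4, and the list counts leave it out. For each list, the median percentile, its order-statistic 95% interval over the probe sets, and the number of probe sets in the top 10% of their array were computed. The median was set against 10000 random lists with as many probe sets from each array, drawn with replacement from single-gene probe sets outside the list. The random lists did not keep the probe sets of a gene together. On simulated data, 5% of 40 unchanged lists of 20 probe sets fell outside the central 95% of random lists. Lists set to 2, 4 or 8 times the median of the array's values above 0 all lay above that range (100%, 40 lists for each fold, 29711 probe sets). Every member was raised, without the zeros, negative values and disagreeing probe sets of the measured lists. The 100% was therefore nearly fixed in advance and does not carry over to them. Fewer random lists were drawn there.

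The genes named were, for each list, the 3 with the highest percentile and the 1 with the lowest, a gene standing at its highest probe set, and the 5 highest single-gene probe sets of each array. INSR, IRS1, AKT2, SLC2A4, PTPN1, GSK3A and the control genes were added by the same rule. Controls were compared over the 5 arrays as the log2 SD of each control probe set above 0 on all arrays (35 of 58), after scaling each array to the 75th percentile of its non-control values. The 3 prime to 5 prime ratios of actin and GAPDH were averaged over the arrays. Genes with single-gene probe sets on 2 designs were compared by Spearman rho of their mean percentiles, with 100 shuffles of genes.

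Alternatives covered the scaling of the controls (none, a mean trimmed by 2% at each end, the median of values above 0), controls above the floor only, the middle in place of the 5 prime probe set, and other noise floors. They also covered, for the lists, the top 25% in place of the top 10%, 1 value per gene, removal of probe sets whose ID marks shared or incomplete probes, ranks among single-gene probe sets or among those above the floor, HuFL alone, and each array left out. Leaving out the HuFL values of 0 and scaling to the controls were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.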

Results

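RNA from a single pool of biopsies of the human vastus lateralis, a large muscle of the thigh that holds both fast and slow fibres, was hybridised once to each of 5 oligonucleotide array designs. The labels name the pool as insulin sensitive pool 4. The designs were the 4 arrays of the Hu35K set (subA, subB, subC and subD), whose probe sets were largely built from expressed sequence tags, and HuFL, built largely from named full-length genes. Each design carried between 7071 and 8876 probe sets besides the 58 control probe sets of the array maker, and 42553 such probe sets were measured in all. Of these, 29711 named a single gene, and they covered 14746 genes. All 5 arrays measured the same RNA, so they were technical measurements of 1 biological sample, and no comparison between insulin sensitive and other subjects could be made. Other groups were not analysed here. What the design allowed was a description of which transcripts gave signal in insulin sensitive muscle, and of how the array designs compared on the controls and genes they shared. The deposited values were intensities on a linear scale. Signals are given as deposited, together with the percentile of the probe set within its own array. Probe sets differ in brightness, so a percentile describes signal and gives no order of transcript abundance between genes.

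The first question was which proteins of muscle and of energy metabolism stood among the strongest signals. Genes of the contractile apparatus and of mitochondrial and glycolytic energy supply stood high within their arrays. Of 335 measured genes in the 12 pathway lists, 257 (76.7%) had at least 1 probe set in the top 10% of its array, against 2828 of all 14746 genes (19.2%). A gene with many probe sets has more chances to reach the top 10%, in the lists as among all genes. The median percentile of 10 of the 12 pathway lists exceeded that of every one of 10000 random lists with as many probe sets from each array. With 1 pool there was no replicate of the condition, and these percentiles describe the arrays without a p-value.

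Proteins of the sarcomere, the contractile unit of striated muscle, were among the strongest signals. Of 28 measured genes of the sarcomere and shared muscle protein list, 23 reached the top 10%, and the median of its 54 probe sets was percentile 96.0 (95% interval over the probe sets 92.3 to 98.4). MYOZ1, which anchors calcineurin at the Z-disc, gave the highest signal of subB outside the controls, 5000 against a noise floor of 203. PDLIM3, a Z-disc protein, followed with 3749 and SMPX, a small protein of striated muscle, with 3174 on the same array. MYBPC1, a myosin-binding protein of slow fibres, stood lowest in the list because its single probe set was listed at 0 on HuFL. In all, 7 probe sets of this list were listed at 0 there, among genes that skeletal muscle is known to use, and such values are given only as listed.

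Transcripts of fast and of slow fibres were both strong. Of 12 measured fast fibre genes, 10 reached the top 10%, with a median at percentile 99.8 over 17 probe sets (interval 99.5 to 99.9). The calcium-storing protein CASQ1 gave 5644 on subC against a floor of 281.3. The fast myosin-binding protein MYBPC2 gave 15532 and the fast sarcoplasmic calcium pump ATP2A1 gave 15220 on HuFL, against a floor of 631.2. The calcium buffer PVALB was the lowest of the list, with a signal of 81 on HuFL that lay under the floor. Of 10 measured slow fibre genes, 8 reached the top 10%, with a median at percentile 99.1 over 17 probe sets and a wide interval of 74.1 to 99.9. The slow troponins TNNC1 and TNNT1 gave the highest signals outside the controls of HuFL (16563) and of subC (8465), and the slow fibre calcium pump ATP2A2 gave 11203 on subD. The 4 probe sets of ATP2A2 diverged, since the others gave 233 on HuFL and -7 and 55 on subB. MYL2, the slow regulatory light chain, was listed at 0 on HuFL.

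Enzymes of energy supply stood close to the contractile proteins. Oxidative phosphorylation had 59 of 63 measured genes in the top 10% and a median at percentile 97.7 over 114 probe sets (interval 96.5 to 98.4). UQCRQ of the cytochrome bc complex gave 12459 and NDUFA1 of the NADH dehydrogenase complex gave 12382 on subA, where the floor was 735. ATP5MC3, which encodes a ring subunit of the ATP synthase, gave 3736 on subB and 7463 on HuFL, while 3 other probe sets of this gene on subB gave 72, 73 and 75. NDUFB2 was lowest in the list, at 14 on subA. Glycolysis and glycogen metabolism had 21 of 25 genes in the top 10% and a median at percentile 95.5 over 51 probe sets (interval 91.7 to 97.8). GAPDH gave 10128 on subA, 11779 on HuFL and 3443 on subC, but 173 on subD, under the floor. Its probe sets on subA, HuFL and subC have IDs that mark shared or incomplete probes, and that on subD does not. The aldolase ALDOA gave 11820 on HuFL. The lactate dehydrogenase LDHA gave 2754 on subC but 37 on subD, and was listed at 0 on HuFL. The highest probe set of the phosphorylase kinase subunit PHKA1 gave 46 on subC, under the floor. Without probe sets whose ID marks shared or incomplete probes, the median of this list was percentile 77.3.

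The citrate cycle and pyruvate dehydrogenase list had 16 of 22 genes in the top 10% and a median at percentile 88.7 over 43 probe sets (interval 84.3 to 92.8). Its strongest genes were the malate dehydrogenases MDH2 (4359 on subD) and MDH1 (8493 on HuFL, but under the floor on subB) and the succinyl-CoA ligase subunit SUCLG1 (2109 on subA). On subA, other probe sets of MDH2 gave 1280, above the floor, and 541, under it. SUCLG1 gave 968 from another probe set on subA, above the floor, and 522 on HuFL, under it. DLAT of the pyruvate dehydrogenase complex was listed at 0. Fatty acid uptake and oxidation had 16 of 23 genes in the top 10% and a median at percentile 93.3 over 38 probe sets (interval 87.3 to 95.6). The fatty acid transporter CD36 gave 1176 on subB, the electron transfer flavoprotein subunit ETFB 529 on subB and the acyl-CoA dehydrogenase ACADM 5774 on HuFL. UCP2, an uncoupling protein of the inner mitochondrial membrane, gave -54 on HuFL.

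**Figure D1:**
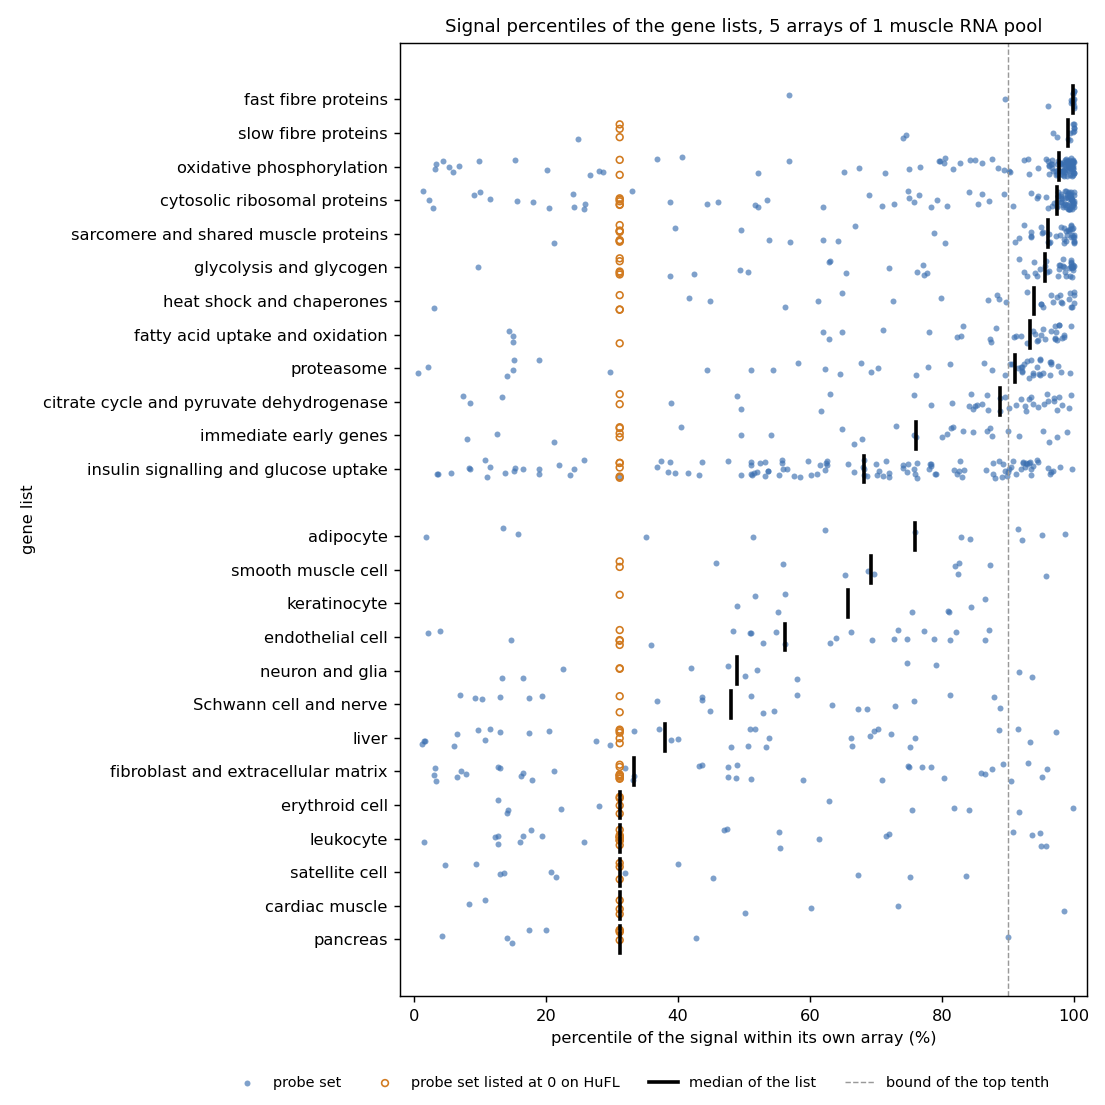
Each point is 1 single-gene probe set, placed by the percentile of its signal within its own array (horizontal axis, %), for the 25 gene lists (vertical axis; 12 pathway lists above, 13 cell type lists below, each ordered by its median). Black bars are list medians, open circles are probe sets listed at 0 on HuFL (percentile 31.2), and the dashed line is the 90th percentile; the medians of 9 pathway lists and of no cell type list lie to its right.

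Insulin signalling and glucose uptake, the pathway named by the pool's phenotype, stood lower within the arrays than the metabolic enzymes. Of 38 measured genes 16 reached the top 10%, and the median of 127 probe sets was percentile 68.1 (interval 58.5 to 74.1), above 99.97% of the random lists. The phosphatase PTPN1, which dephosphorylates the insulin receptor, gave 1479 on subB against a floor of 203. Its other probe sets gave 290 and 161 on HuFL and -124 on subD, all under the floors of those arrays. PRKAA2, a catalytic subunit of the AMP-activated kinase, gave 426 on subB and 285 on subC, above the floors of those arrays, and 53 on HuFL and 64 on subA, under the floors. The receptor adaptor GRB10 was above the floor on each of its 3 arrays, with 839 on HuFL, 547 on subC and 678 on subD. The kinase PRKCZ stood lowest, with 1 probe set listed at 0 on HuFL and the other at -23 on subD.

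The genes of the proximal insulin pathway were spread around the noise floor. The insulin-regulated glucose transporter SLC2A4 gave 947 on HuFL, above the floor of 631.2, and 306 and 183 from its other probe sets, under the floors. The receptor substrate IRS1 gave 889 on subA and 748 on HuFL, both above the floor, while 1 of its other probe sets gave -130. The kinase GSK3A lay just above the floor on both of its arrays, with 231 on subB and 638 on HuFL. The subB value came from a probe set marked as shared within a gene family. The kinase AKT2 gave 548 on HuFL (percentile 87.7), under the floor but above the floor at the mirrored 5th percentile, 232. Only 10.6% of HuFL probe sets exceeded the main floor, so a signal under it was not shown to be absent. The insulin receptor INSR had 7 probe sets, and its highest by percentile gave 91 on subC, under the floor of 281.3. It was also under the floor at the mirrored 5th percentile there, 99.

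Transcripts of protein synthesis, protein breakdown and folding were also strong. Cytosolic ribosomal proteins had 50 of 57 measured genes in the top 10% and a median at percentile 97.3 over 101 probe sets (interval 89.3 to 98.1). RPS27 gave the highest signal of subA outside the controls (13769), RPL41 gave 10002 on subD and RPS15 gave 5227 on subC. All 3 were listed at 0 on HuFL. Another RPS15 probe set on subC gave -152, and RPL28 gave -235 on subC. The ribosomal median was percentile 98.6 on HuFL alone and percentile 79.3 without HuFL. The proteasome had 22 of 25 genes in the top 10% and a median at percentile 91.1 over 48 probe sets (interval 76.05 to 93.2). PSMD11 gave 1569 on subC, 849 on HuFL and 240 on subB, above the floors, and 108 on subA and -2 on subB, under them. PSMA4 gave 1705 on subD and PSMA7 gave 1709 on subA (but -186 on subC), and PSMC4 was lowest in the proteasome list with 242 on subA. The proteasome median was also lower without HuFL, at percentile 66.1.

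Heat shock proteins and chaperones had 12 of 18 genes in the top 10% and a median at percentile 93.9 over 32 probe sets (interval 72.6 to 97.9). The small heat shock proteins HSPB1 (11391 on subD), HSPB6 (11008 on subD) and HSPB7 (3170 on subB), known to be abundant in striated muscle, led the list. The HSPB6 value came from a probe set marked as shared within a gene family. The other HSPB6 probe sets gave 1390 and -204 on subD and 793 on subC, where the floor was 281.3. Another HSPB1 probe set on subD gave 211, and that on HuFL gave 8958, above the floor. HSP90AA1 was listed at 0 on HuFL. Immediate early genes, which are induced within minutes of stress, had 4 of 14 genes in the top 10% and a median at percentile 76.1 over 31 probe sets (interval 54.1 to 84.6), above 99.8% of the random lists, and above 96.75% of random lists of genes by the highest probe set of each gene. JUN gave 2577 and IER2 gave 1343 on subD, while their other probe sets gave 250 and 257 on HuFL, 392 on subA and 50 on subD, under the floors. JUND was above the floor on both of its arrays, with 297 on subB and 1393 on HuFL, and IER3 gave -72 on HuFL. The IDs of both JUND probe sets mark shared or incomplete probes.

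The strongest named signals of each array included genes outside the lists. NDRG2, a gene of the N-myc downstream regulated family, gave 11519 and 5268 on subA but 140 on subB, under the floor. The fast myosin light chain MYL1, a list gene, gave 10967 on subA. CHCHD10, a protein of the mitochondrial intermembrane space, gave 4624 and PPP1R3C, which targets a phosphatase to glycogen, gave 3427 on subB. ANKRD23, a muscle ankyrin repeat protein, gave 5951 and CMYA5, a large protein of the muscle costamere, gave 5693 on subC. The CMYA5 value came from a probe set marked as shared within a gene family, and its unmarked probe sets gave 3328 on subA and 599 on subB. TXNIP, a thioredoxin-binding protein known to lower glucose uptake, gave 9993 on subD. The translationally controlled protein TPT1 gave 16274 on HuFL, with 1535 and -72 on subB.

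The next question was which other cell types of a biopsy could be seen. Markers of other cell types stood lower within their arrays than the muscle and metabolic genes. Of 113 measured genes in the 13 cell type lists, 18 (15.9%) reached the top 10%, against 19.2% of all 14746 genes. No median of these lists exceeded all random lists, and 46 of their 264 probe sets were listed at 0 on HuFL, which set the medians of 5 lists to the percentile of that value, 31.2. Medians with these probe sets left out, a choice made after seeing the data, are therefore given where they differ by over 5 points, and for satellite cells.

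Over all 5 arrays, adipocyte markers had the highest median of the cell type lists, percentile 75.9 over 13 probe sets (interval 15.8 to 92.2). The list stood above 97.0% of the random lists, and above 90.4% of random lists of genes by the highest probe set of each gene. By that last measure the fibroblast (97.6%) and smooth muscle (91.7%) lists stood higher. On HuFL alone, smooth muscle markers had a higher median, percentile 73.7 against 72.6. Without the HuFL values of 0, keratinocyte markers, none above the noise floor, came close to the adipocyte median, at percentile 75.4 against 75.9. The complement factor CFD gave 2417 on subA and 1344 on HuFL, both above the floor, and -52 from another probe set on subA. The lipid droplet coat protein PLIN1 gave 580 on subD and the fatty acid binding protein FABP4 gave 764 on HuFL, both above the floor. CIDEC, a lipid droplet protein, gave 42 on subD. Smooth muscle markers had a median at percentile 69.2 over 12 probe sets and 74.3 without the values of 0. Their smooth muscle myosin MYH11 gave 955 on subD, above the floor, and 364 and 28 on HuFL, under it, whereas LMOD1 (534) and SMTN (379) were under the floor of HuFL and ACTA2 was listed at 0.

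Fibroblast and extracellular matrix genes had a median at percentile 33.3 over 45 probe sets, above 0.875% of the random lists. Without the values of 0 the median was percentile 47.5, above 19.3% of the random lists. By the highest probe set of each gene, the median was percentile 83.1, above 97.6% of random genes treated alike. The collagen COL1A2 (969), the matrix glycoprotein SPARC (857) and the proteoglycan DCN (640) were above the floor of 381.3 on subD. All other probe sets of these 3 genes were under their floors, the highest of them giving 262 on subA for COL1A2, 545 on HuFL for SPARC and -31 on subB for DCN. COL6A1 stood lowest, listed at 0 on HuFL and below 0 on 3 other arrays, in a tie with COL1A1, whose probe sets were listed at 0 on HuFL. Endothelial markers had a median at percentile 56.2 over 27 probe sets and 63.0 without the values of 0, and none of the 27 was above the noise floor. Their strongest genes were the receptor FLT1 (523 on HuFL), VWF (338 on subD) and EMCN (130 on subC), and the receptor KDR gave -440 on HuFL.

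Erythroid markers had a median at percentile 31.2 over 15 probe sets, at percentile 62.9 without the values of 0 and at percentile 75.5 without the HuFL array. The globin HBA2 gave 3491 on subC, from a probe set marked as shared within a gene family, and the haem synthesis enzyme ALAS2 gave 538 on subD, with its other probe sets under the floors (478, 128 and -55). SLC4A1, the red cell anion exchanger, gave 166 on subD and AHSP gave 14 on subA. Leukocyte markers had a median at percentile 31.2 over 29 probe sets, above 2.5% of the random lists. Without the values of 0 the median was percentile 38.1, above 8.995% of the random lists. LYZ gave 1596 on HuFL, with 1309 and 1252 from 2 further probe sets there, all 3 marked as shared within a gene family and above the floor. Its remaining probe sets gave 33 on HuFL and 244 on subC, under the floors. CD3E (998) was above the floor on HuFL, MS4A1 gave 74 on subC and CD14 gave -521 on HuFL.

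Markers of Schwann cells and nerve, satellite cells, keratinocytes and endothelial cells included no probe set above the noise floor. With a floor at the mirrored 5th percentile, 5 of 24, 2 of 15, 5 of 10 and 8 of 27 probe sets lay above it. That floor was exceeded by 18.0% to 27.4% of all probe sets of an array. Schwann cell and nerve markers had a median at percentile 48.0 over 24 probe sets, led by MBP (208 on subC), NCAM1 (250 on HuFL) and PMP2 (116 on subD), with S100B lowest (20 on HuFL). Satellite cell markers had a median at percentile 31.2 over 15 probe sets and percentile 28.7 without the values of 0. They were led by MET (144 on subC), CDH15 (240 on HuFL) and PAX3 (58 on subC). The lowest gene placed in this list was CHRNA1 (-111 on HuFL). Keratinocyte markers had a median at percentile 65.8 over 10 probe sets and 75.4 without the values of 0, led by KRT10 (504), KRT1 (489 on subA) and KRT14 (342), with IVL listed at 0.

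The remaining lists stand for tissues outside a thigh biopsy. Cardiac muscle markers had a median at percentile 31.2 over 9 probe sets, percentile 47.3 without the values of 0 and percentile 98.5 without the HuFL array, where 1 probe set remained. MYL4, an atrial and embryonic light chain, gave 2033 on subD from a probe set marked as shared within a gene family and was listed at 0 by its 3 HuFL probe sets. NPPB (217), TNNI3 (48) and NPPA (-132) were under the floor. Liver markers had a median at percentile 38.1 over 40 probe sets, above 2.88% of the random lists, although AMBP (1311), APOC3 (664) and TTR (534) exceeded the floor on subD. Their other probe sets did not: AMBP was listed at 0 and APOC3 gave 253 on HuFL, and TTR gave -189 on HuFL, 248 on subA and -19 on subB. The apolipoprotein APOA1 was listed at 0 by 1 probe set and lay below 0 in its other 4. Neuron and glia markers had a median at percentile 48.9 over 14 probe sets. They were led by SYN1 (692 on subD but 19 on subC, and listed at 0 on HuFL), GFAP (788 on HuFL, but -30 on subC) and SYP (201 on subD), with ENO2 at -40. Pancreas markers had a median at percentile 31.2 over 11 probe sets, percentile 20.1 without the values of 0 and percentile 14.2 without the HuFL array. The somatostatin gene SST gave 664 on HuFL, CPA1 gave 17, INS was listed at 0 and PNLIP gave -50.

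A further question was how much of each array carried signal. Between 24.5% of probe sets (subA) and 38.6% (HuFL) were at or under 0, with 32.6% on subB, 30.6% on subC and 30.2% on subD. On HuFL 1054 probe sets were listed at exactly 0, against 10 on subA, 84 on subB, 69 on subC and 70 on subD. Without them, 27.9% of HuFL probe sets were below 0. The share above the noise floor was 9.37% on subA, 6.44% on subB, 7.81% on subC, 11.8% on subD and 10.6% on HuFL. These shares depended on the floor and lay between 18.0% and 27.4% with a floor at the mirrored 5th percentile and between 26.6% and 39.3% with a floor at the highest bacterial control that was not spiked.

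**Figure D2:**
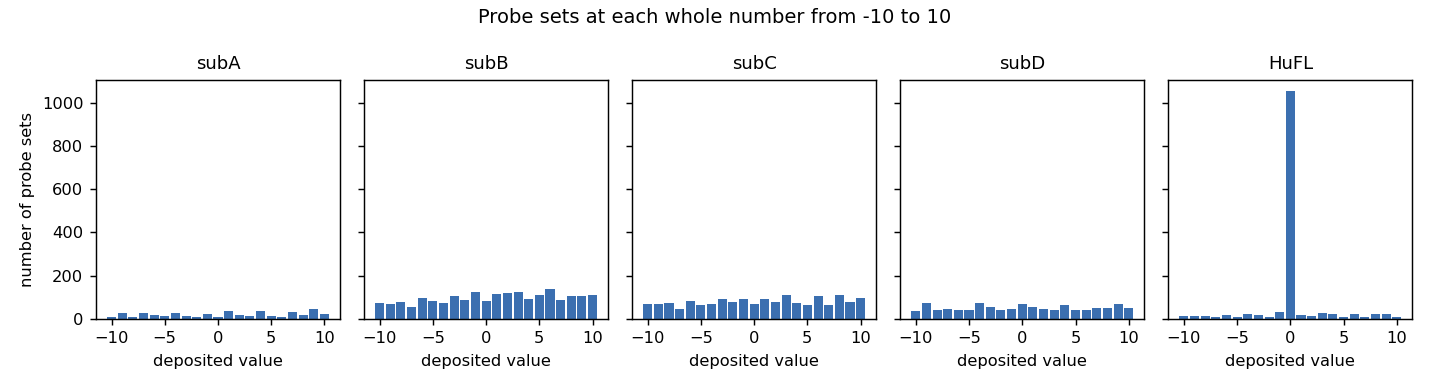
Number of probe sets (vertical axis) at each deposited whole number from -10 to 10 (horizontal axis, intensity units) on each of the 5 arrays, controls left out. HuFL holds 1054 probe sets at 0 between 30 at -1 and 19 at 1, and no such excess is seen on the other 4 arrays.

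The control probe sets, present under the same ID on every array, showed how the designs compared. GAPDH, a glycolytic enzyme used as an endogenous control, gave 17539 at its 5 prime probe set on subA, 6548 on subB, 7104 on subC, 12065 on subD and 15609 on HuFL. The spiked CreX transcript, which is added during preparation, ran parallel to it, with 16768, 5747, 7316, 11207 and 15304. Scaled to the 75th percentile of each array, the 35 control probe sets above 0 on all arrays had a median log2 SD over the 5 arrays of 0.46 (n = 5). Without scaling it was 0.72, and scaled to the 15 controls above the floor on all arrays, a choice made after seeing the data, it was 0.24. Those 15 are among the 35, which lowers their spread by construction. On the other 20 controls the spread was 0.30, against 0.51 with the 75th percentile.

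**Figure D3:**
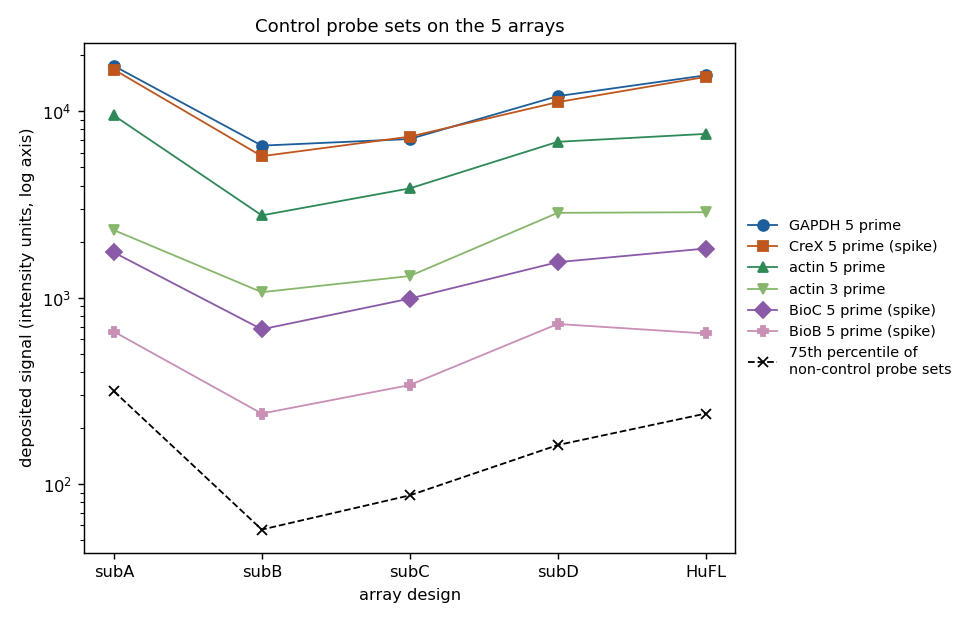
Deposited signal (vertical axis, log scale) of 6 control probe sets and the 75th percentile of the non-control probe sets (dashed) on the 5 array designs (horizontal axis). Lines join the values of 1 probe set; the GAPDH 5 prime signal spans 6548 to 17539 and the 75th percentile spans 57 to 315.

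The ends of the endogenous control transcripts differed in signal in the same direction on every array. The actin 3 prime signal was 0.353 ± 0.068 (SD, n = 5 arrays) of the 5 prime signal, ranging from 0.243 on subA to 0.416 on subD. The GAPDH ratio was 0.671 ± 0.021 (SD, n = 5 arrays). Against the middle probe set, the ratios were 0.647 for actin and 0.992 for GAPDH. These ratios compare different probe sets, so their spread over arrays can be read and their distance from 1 cannot.

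Genes measured on different designs tended weakly to the same percentile. Over the 10 pairs of designs, the Spearman rho across shared genes had a median of 0.175 and ranged from 0.097 (subB and subC, 1185 genes) to 0.257 (subD and HuFL, 1190 genes). In each pair it exceeded the highest of 100 shuffles of genes, narrowly for subB and HuFL (0.111 against 0.109). Without the HuFL values of 0 the subD and HuFL rho was 0.316. Some probe sets carried the same ID on several designs (484 IDs, 466 of them on both subA and HuFL), and without these the median rho was 0.173, a check added after seeing the data. The 466 probe sets with the same ID on subA and HuFL had a rho of 0.362. The median was 0.111 without marked probe sets and -0.17 among genes above the floor on at least 1 design of the pair, a selection that by construction favours opposite ranks. Genes are not independent replicates, and the rho describes these arrays. Probe sets of a gene often disagreed: of 2040 genes with several probe sets and at least 1 in the top 10%, 1129 (55.3%) had another at or below the middle of its array, against 67.8% to 72.5% in 100 shuffles.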

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

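The tests of array brightness and of both explanations for the 3 prime signals were chosen only after the results were seen, as was scaling to the bright controls. Of 15 controls above the floor on all arrays, 1 had an array far from the others after scaling to the 75th percentile: the BioDn 5 prime spike was lowest on subA, by -1.27 on the log2 scale against the mean of the other arrays. Scaled to the bright controls, a scale set by these same 15, 0 of 15 stood apart. The GAPDH 3 prime to middle ratio was lowest on subA, 0.926, with the other 4 arrays between 1.005 and 1.014. Chance marks about 1 in 20 such sets of 5 values where the sets are independent. The 15 controls were not: as a set they were lowest on subA relative to the 75th percentile (-0.59 on the log2 scale, against the mean of the arrays). For the GAPDH ratio, the gap to the nearest value was 0.898 of the range, above the limit of 0.71. A sense-strand probe set at the actin 3 prime end, designed for the strand opposite to that of the other actin probe sets, gave signal above the floor on all 5 arrays, with a mean of 1233 ± 62 (SD, n = 5, bright-control scale) against 326 ± 35 for the strongest other sense-strand control of each array.

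The 1054 probe sets listed at exactly 0 on HuFL included muscle genes such as MYL2 and MYBPC1, and gathered by the first letters of the probe set ID: 47.0% of IDs beginning with X and 39.5% with Z were at 0, against 4.33% with U and 0.403% with HG. Missing values entered as 0 and transcripts below background were weighed. For 330 genes listed at 0 on HuFL and measured on a Hu35K array, the median Hu35K percentile was 54.2 (interval 50.02 to 60.6), close to 54.0 for 2260 genes over 10 units from 0. For 117 genes within 10 units of 0 but not at 0 it was 44.2 (interval 40.2 to 48.2), lower by a difference of 9.95, which argues against transcripts below background as the whole cause. The zeros may therefore be missing values, as a hypothesis, and no biological difference between samples was tested.

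The controls and the 75th percentiles of the arrays moved by different amounts: the 75th percentile differed 5.53-fold between the highest and the lowest array and the bright controls 2.73-fold. After scaling to the controls the highest 75th percentile was still 2.07 times the lowest, but this restates the unequal spans and was no separate test of array brightness, which was left open. Fewer measured transcripts among the probe sets of a design could lower the 75th percentile. For 853 genes above 0 on both subA and subB, the median log2 ratio of subB over subA was -0.32 (interval -0.53 to -0.17) on the control scale, nearer to 0 than the -1.05 of the 75th percentiles, as that explanation predicts. On the same scale, the noise floors of subB over subA had a log2 ratio of -0.44, inside that interval. Only 45 of the 853 genes were above the floor on both arrays. The ratio may therefore largely compare noise and cannot decide, and this explanation stays open by a limit set after the value was seen.

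The actin 3 prime signal was below the 5 prime signal on all 5 arrays, with a highest ratio of 0.416. Unequal brightness of probe sets could give this: the spiked BioDn transcript had a mean 3 prime to 5 prime ratio of 4.26 ± 0.68 (SD, n = 5), farther from 1 than actin on every array. Degraded RNA raises the 3 prime signal relative to the 5 prime signal, and the ratio cannot exclude it, since the brightness of the probe sets differs by an unknown factor. No biological explanation was tested.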

How the results depend on the processing

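Leaving out the HuFL values of 0 and scaling to the spikes or to the bright controls were chosen after seeing the data. Of 25 lists, the median stayed within its 95% interval over the probe sets in 25 without the HuFL values of 0, in 24 among single-gene probe sets, in 24 without marked probe sets, in 21 on HuFL alone and in 17 at the highest probe set of each gene, where all 8 others rose. With the highest probe set of each gene, the medians were 98.5 for the sarcomere, 93.3 for the citrate cycle, 98.8 for oxidative phosphorylation, 87.7 for insulin signalling, 98.95 for ribosomal proteins, 93.7 for the proteasome, 83.1 for fibroblasts and 69.1 for liver; a gene's highest probe set is never below its others, and the median rose in 23 of 25 lists. Without marked probe sets, glycolysis had a median of 77.3, and the cause was not tested. Among single-gene probe sets, fibroblasts had 30.3, the same median as lists set by the HuFL values of 0, such as leukocytes. Ranking only among probe sets above the noise floor lowers by construction the rank of each that remains. In that ranking the medians were 85.2 for the sarcomere, 98.6 for fast fibres, 85.7 for glycolysis, 53.1 for the citrate cycle and 85.98 for oxidative phosphorylation. They were 69.25 for fatty acids, 31.35 for insulin signalling, 40.6 for the proteasome and 47.9 for immediate early genes. Cardiac muscle had 87.25 and pancreas 4.81, each from 1 probe set, and 4 lists had no probe set above the floor. On HuFL alone, the medians were 91.7 for the sarcomere, 98.6 for ribosomal proteins and 93.45 for the proteasome, and the cause was not tested. Endothelial cells had 31.2 there, the percentile of the HuFL values of 0. With each array left out in turn, the medians ranged from 95.2 to 98.6 for the sarcomere, from 79.3 to 97.95 for ribosomal proteins, from 66.1 to 92.1 for the proteasome and from 31.2 to 98.5 for cardiac muscle, and the departures came without HuFL, where cardiac muscle keeps 1 probe set. Within wide intervals, erythroid markers moved to 75.5 and pancreas markers to 14.2 without HuFL. With the top 25% in place of the top 10%, the fold over the expected share fell below its interval in 9 of 25 lists, where the top 25% allows a fold of at most 4, and it was higher in 8 lists, within wide intervals (from 0 to 2.0 for keratinocytes). The share above the noise floor rose under both other floors on every array. With a floor at the mirrored 5th percentile, it was 27.4% on subA, 18.0% on subB, 22.6% on subC, 27.3% on subD and 25.5% on HuFL. With a floor at the highest bacterial control that was not spiked, it was 33.9%, 26.6%, 26.7%, 39.3% and 36.0%. Without the HuFL values of 0, 27.9% of HuFL probe sets were below 0. The control spread was 0.72 unscaled, 0.26 scaled to the spikes and 0.24 scaled to the bright controls (0.27 and 0.30 on the controls outside each scaling set, a measure added after seeing the data), and 0.33 to 0.50 with each array left out, lowest without subA. The ratios to the middle probe set were 0.647 for actin and 0.992 for GAPDH, which are other probe sets. The rho between designs was -0.17 among genes above the floor on at least 1 of both designs, a selection that by construction favours opposite ranks, and 0.111 without marked probe sets, whose cause was not tested. Signal over background limited the results on most genes, though not those on the bright controls: under the main floor, at most 11.8% of the probe sets of an array lay above it.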

Other observations

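The tests and gene groups here were chosen only after the values were seen. Of 336 single-gene probe sets in the top 1% of their array, 124 (36.9%) were matched to the lists, against 3.16% of all single-gene probe sets. In that top 1%, 30 genes appeared on at least 2 designs, against 0 to 7 in 100 shuffles of genes, and 3 appeared on at least 3 designs. Of the 30, 13 were matched to the lists, such as MYL1, TNNI2, LDB3 and TRDN, and 17 were not. The unmatched genes included COXFA4, which is NDUFA4 of the oxidative phosphorylation list under its newer symbol. KLHL41, a muscle kelch protein, gave 3489 on subA, 2755 on subB and 4823 on subD. PDE4DIP, a scaffold protein of the centrosome and Golgi, gave 7304 on subA, 1632 on subB and 5981 on subD. CMYA5 gave 3328 on subA and 5693 on subC, and ADSS1, the muscle adenylosuccinate synthase, gave 3636 on subA and 5507 on subD. The ubiquitin ligase WWP1 gave 5201 on subA and 2787 on subB.

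Genes of the oxidative phosphorylation list were also counted by respiratory complex, and the complexes were not compared by a test. Complex I had 27 of 29 measured genes in the top 10%, complex III 7 of 7, complex IV 11 of 11 and the ATP synthase 14 of 15. The median percentiles were 97.7, 96.7, 97.99 and 97.9, over 50, 12, 20 and 30 probe sets. Complex II was counted in the citrate cycle list, where SDHA gave 2987 and SDHC 750 on HuFL and SDHD gave 855 on subA and 671 on subD.

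A hypothesis was that values far below 0 follow the transcript, for example through sequences that bind the mismatch probes, and so would recur on another design. Of 326 single-gene probe sets below the mirrored floor, genes met this on 2 or more designs in 3 cases (PTMS, TULP1 and ITPRIPL2), within the 0 to 7 of 100 shuffles. TULP1 met this through the same probe set ID on HuFL and subA. The shuffled median was 2, so counts this small cannot decide whether probe sets of a transcript share such a property.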
